A study of Homo sapiens with 8 samples.

How the data were processed

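Gene expression was measured in SAS cells, a line derived from human tongue cancer, with 8 Agilent one-colour microarrays. Cells grown on a standard plate (attached, 4 arrays) were compared with cells grown on a low-attachment plate (detached, 4 arrays), each after 72 h in culture. Total RNA was labelled with Cy3, per the labels' protocols. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

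The deposited scanner files hold linear intensity values from Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes, with a background-corrected processed signal for each spot. Each array held 62976 spots, of which 2075 were controls. The deposited value table held linear intensity values too: all 58201 of its rows equalled the mean processed signal of a probe within a relative tolerance of 1e-05, with no scaling or centring between arrays. Its column medians ranged from 5.56 to 10.9. The build and coordinates behind the probes are not given in the sources used here.

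Control spots were left out, as were the 45 to 91 spots per array that the software had called outliers. Spots of one probe were averaged, log2 was taken, and the 75th percentile of each array was subtracted. Signals are therefore given in log2 units relative to that percentile. Between 36.8% and 45.4% of probes were well above background on an array. The percentile over all probes was kept as the main setting, as fixed before the data were examined, and the percentile over probes detected on all arrays was an alternative. No spot was saturated (0 on every array). A probe was tested if it was well above background on all 4 arrays of at least 1 group.

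The scanner files carry accessions but no gene symbols, although the design fixed beforehand had assumed symbols. Accessions were therefore matched without versions to a RefSeq gene table of assembly GRCh38.p14, used for names only. Of 58201 probes, 31104 had 1 symbol and 27097 had none, and 22439 symbols were represented. None of the 9747 probes with Ensembl transcript identifiers could be named in this way (0 matched). For each gene the tested probe with the highest mean signal was used, and unnamed probes were kept as features of their own. Of 3576 genes with more than 1 tested probe, 229 had probes called in opposite directions.

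Differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 6 residual and 3.34 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 counted as changed. Where a gene was not well above background on any array of the dimmer group, its fold is a bound, written as at least N-fold. This is the mean of the brighter group over the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

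Before the data were examined, 42 gene lists were fixed, including markers of other cell types, and 41 had the 5 tested members needed for a test. Lists were tested with camera and a preset correlation of 0.01, adjusted over the 41 lists. Camera with an estimated correlation and fry were alternatives. Each list's median was also set against 10000 random lists matched on mean signal in 20 bins, as a description of these arrays. Named genes were chosen by a rule fixed beforehand. It took the 12 largest rises and 12 largest falls past the test with no overlap between groups and detection on all 4 arrays of the brighter group. Genes with only a bound were ranked by it, and symbols of uncharacterised loci were left out. From each list it took up to 2 members with the largest rise and 2 with the largest fall, and all members where a count was 5 or fewer. For a list with neither, it took the 2 brightest members. The text gives a selection of the genes this rule named.

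All 8 arrays lay on 1 slide, with attached samples in row 1 and detached samples in row 2, so a slide block was not applicable and array row and group cannot be told apart. Replicate numbers are shared by the groups in the labels. Deviations from the group means correlated between same-numbered arrays at 0.27, 0.21, 0.18 and 0.45 for replicates 1 to 4, so the numbers were taken to pair the samples. This pairing rests on the values, since the labels do not say what a number stands for, and attached replicate 2 correlated more with detached replicate 1 (0.29). Arrays with the same number also lay in the same column of the slide, so a pairing of samples and an effect of position cannot be told apart. The fit without the block was the main one, and the fit with the replicate block an alternative. All 35 splits of the 8 arrays into 4 and 4 were fitted as well.

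Alternatives covered the background correction, scaling, filter, probe choice, variance model, array weights, threshold and left-out replicates. The planned normexp correction on the mean signal could not be run because that column is absent from the files used, and normexp with an offset of 50 on the median signal took its place. That setting, scaling on 7 spike-ins, cyclic loess, and leaving out the arrays with the lowest and the highest 75th percentile together were chosen after seeing the data. The steps were tested on simulated data of detached against attached arrays with 19886 features. Of 100 features shifted by 0.5 on the log2 scale 33 were recovered, of 50 shifted by 1.0 38, and of 50 shifted by 2.0 49. Of 138 calls, 10 were other members of a list shifted as a whole by 1.0, and 8 (5.80%) were false, and the only list called of 41 was the 1 shifted list. The simulated noise was independent between features and few features were shifted. In the data the estimated correlation among members of a list ran from -0.028 for p53 targets to 0.90 for ribosomal proteins. The simulation therefore does not test false calls of lists with correlated members.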

Results

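The transcriptome of SAS tongue cancer cells was profiled after 72 h on a standard plate, where the cells attach, and on a low-attachment plate, where they stay detached. The comparison asks which transcripts differ between attached and detached cells. Each group held 4 arrays. The 75th percentile of the processed signal was 179, 102, 172 and 177 intensity units on attached arrays 1 to 4, and 228, 197, 211 and 275 on detached arrays 1 to 4. Attached arrays had 21403 to 24228 probes well above background and detached arrays 25198 to 26426. The number of arrays limits the precision.

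**Figure D1:**
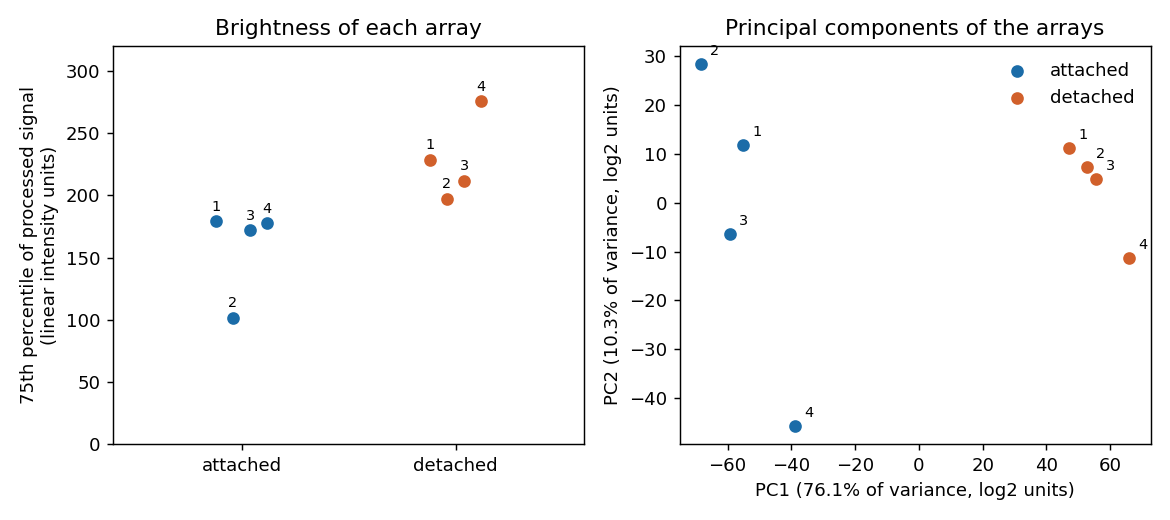
Left, the 75th percentile of the processed signal (linear intensity units) of each array, with the replicate number beside each point. Right, the first 2 principal components of the normalized log2 signals, where PC1 held 76.1% and PC2 10.3% of the variance and the groups lay on opposite sides of PC1.

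Arrays of one group resembled each other more than those of the other group. Across tested features, which are not independent replicates, Pearson's r was 0.982 to 0.993 among attached arrays and 0.994 to 0.997 among detached arrays. Between the groups it was 0.946 to 0.970. No 2 arrays held identical values.

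Detached cells had far higher transcripts of several epidermal and inflammatory proteins. S100A7, an antimicrobial calcium-binding protein of the epidermis (NM_002963), rose from 2.37 ± 0.18 to 7.21 ± 0.23 on the normalized log2 scale (SD, n = 4), a 28.6-fold rise with a log2 difference of 4.84 (SE 0.14, adjusted p = 1.4e-07). KRT1, a keratin of the suprabasal epidermis, was 20.8-fold higher, although only 1 of 4 attached arrays detected it. PRODH, which starts the breakdown of proline, was 23.1-fold higher, although another of its probes had a log2 difference of 3.59. TNFSF10, the death ligand TRAIL, rose 15.1-fold, from 0.44 ± 0.34 to 4.35 ± 0.23, and UBD, a ubiquitin-like modifier inducible by interferon, rose 16.9-fold with detection on 1 of 4 attached arrays. The chemokine CCL2 rose 12.4-fold and the acute-phase protein SAA2 10.8-fold, although another SAA2 probe had a log2 difference of 2.29. The other large rises were those of STON1 (19.0-fold, detected on 3 of 4 attached arrays), GPRC5D-AS1 (11.9-fold), TNNT3 (11.7-fold) and MAB21L4 (10.7-fold). The log2 differences of the GPRC5D-AS1 probes ran from 3.47 to 5.33. ATP6V1B1, a subunit of the vacuolar proton pump, was not well above background on any attached array and was at least 14.4-fold higher. S100A7 and SAA2 have close relatives (S100A7A, SAA1) whose transcripts the probes may not separate, so these values are uncertain as to the gene.

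Among the transcripts that fell, VIM, the intermediate filament protein of mesenchymal cells, went from 2.60 ± 0.27 to -0.80 ± 0.29 (SD, n = 4), a 10.5-fold fall (log2 difference -3.40, SE 0.18, adjusted p = 1.5e-06). CDH11, a cadherin of mesenchymal cells, fell 7.95-fold, and LPXN, the focal adhesion protein leupaxin, fell 8.57-fold. IL1RL1, the receptor of interleukin-33, fell 10.4-fold and was detected on 3 of 4 detached arrays. The protease inhibitor SPINK1 was not well above background on any detached array and was at least 7.58-fold lower. The largest fitted falls among the rest were those of SH2D1B (15.1-fold, detected on 1 of 4 detached arrays), MARCHF4 (13.9-fold, detected on 3 of 4) and TRHDE-AS1 (13.2-fold). ST3GAL6-AS1 (9.07-fold, detected on 2 of 4), PLPP4 (8.86-fold), KRTAP2-3 (8.45-fold) and TNIK (7.60-fold) completed the set. Another TNIK probe had a log2 difference of -2.01. All 24 of these genes kept their direction and their call under each of the 24 or 25 other settings that gave them a value, but not their size. With normexp, whose offset compresses the differences of dim probes, the log2 difference of KRT1 went from 4.38 to 1.94, that of UBD from 4.08 to 2.02 and that of SH2D1B from -3.92 to -1.70. That of ATP6V1B1 was then 2.08 and that of SPINK1 -1.35, so their bounds hold for the processed signal and not for normexp.

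**Figure D2:**
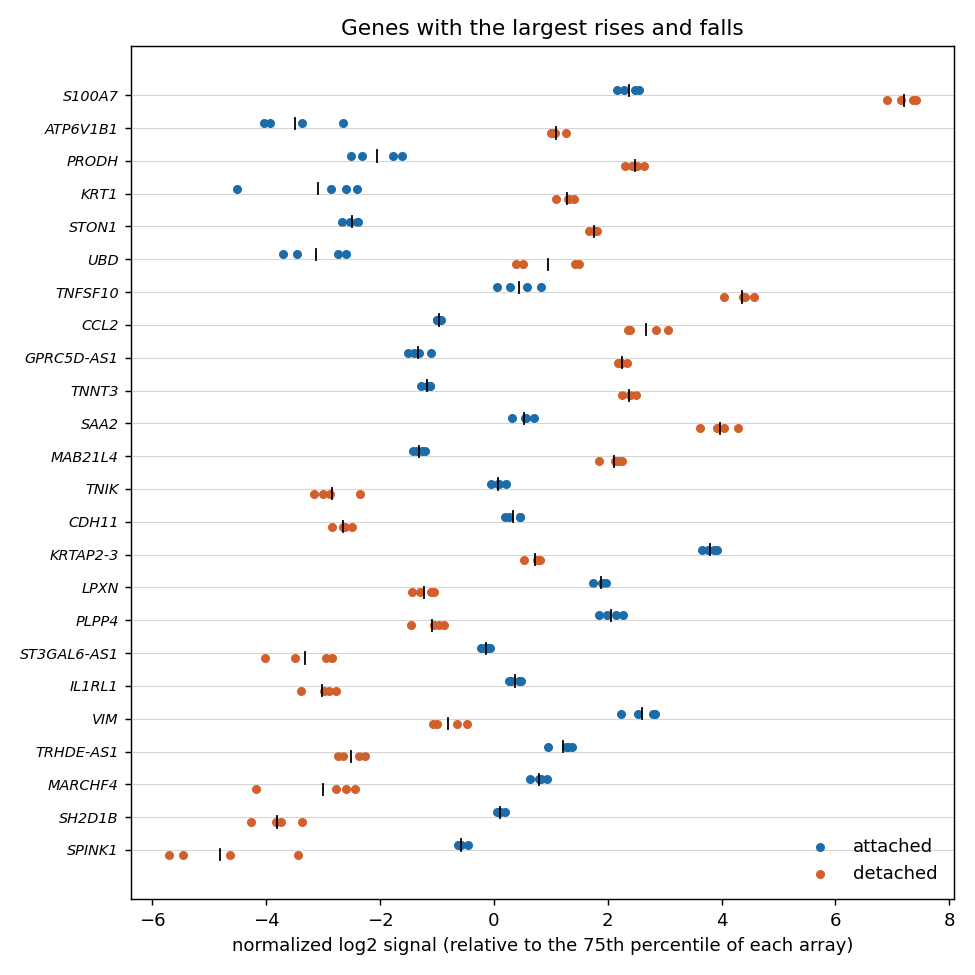
Normalized log2 signal (relative to the 75th percentile of each array) of the 24 genes with the largest rises and falls, with a point per array and a black line at each group mean (n = 4 per group). The group means of S100A7 were 2.37 and 7.21, and in each of the 24 genes the groups did not overlap.

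Over all genes, 13203 of 19886 tested features changed with limma, 5119 higher and 8084 lower in detached cells. Of these, 3153 changed at least 2-fold, 1748 higher and 1405 lower. The groups did not overlap in 11832 features (59.5%), where chance gives 2.86%. The balance of rises and falls depended on the scaling. Relative to the main setting, the median of all features moved by 0.16 with quantile normalization, 0.25 with the percentile over detected probes, 0.20 with cyclic loess, 0.59 without scaling and 0.84 with scaling on the spike-ins. The split of higher against lower calls was 6055 to 6178 with quantile normalization, 7314 to 5028 with the percentile over detected probes and 6510 to 5776 with cyclic loess. It was 7727 to 713 without scaling and 7567 to 169 on the spike-ins. Directions below are therefore relative to the 75th percentile of each array, and falls smaller than those shifts can turn with the setting. With quantile normalization and cyclic loess the shift varied with brightness, so larger falls could turn too. The median of the ribosomal protein list, for example, went from -0.50 to 0.26 with cyclic loess.

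The difference between the groups decreased with brightness. In 4 equal bins of features from dim to bright, the median log2 difference was 0.10, -0.039, -0.16 and -0.47. From the dimmest to the brightest bin it fell by 0.57 on the log2 scale, but by 0.12 with quantile normalization, 0.063 with cyclic loess and 0.073 with normexp, and without the filter on dim probes it rose by 0.40. List medians are accordingly set beside those of random lists of equal brightness.

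With camera, 13 of the 41 lists moved, 6 up and 7 down. No call held with an estimated correlation (0 of 41 lists at an adjusted p under 0.05, 3 at an unadjusted p under 0.05), whereas fry, which does not compare a list with other genes, called 33. For each called list except the ribosomal proteins, the estimated correlation gave the highest adjusted p of the settings run. A higher correlation alone does not account for these losses. The xenobiotic list was estimated at -0.023, below the preset 0.01, yet its unadjusted camera p went from 0.00279 to 0.0198. That of the mesenchymal list, estimated at 0.014, went from 0.0144 to 0.0547. The remaining cause was not tested. Counts of risen and fallen members adjusted over the list alone equalled those over all genes in all but 3 lists. These were the list of ribosomal proteins, with 27 fallen in place of 26, that of ATF4 targets, with 17 in place of 16, and that of NRF2 targets, with 8 risen in place of 7. The members of every called list are shown in the plot of list members.

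**Figure D3:**
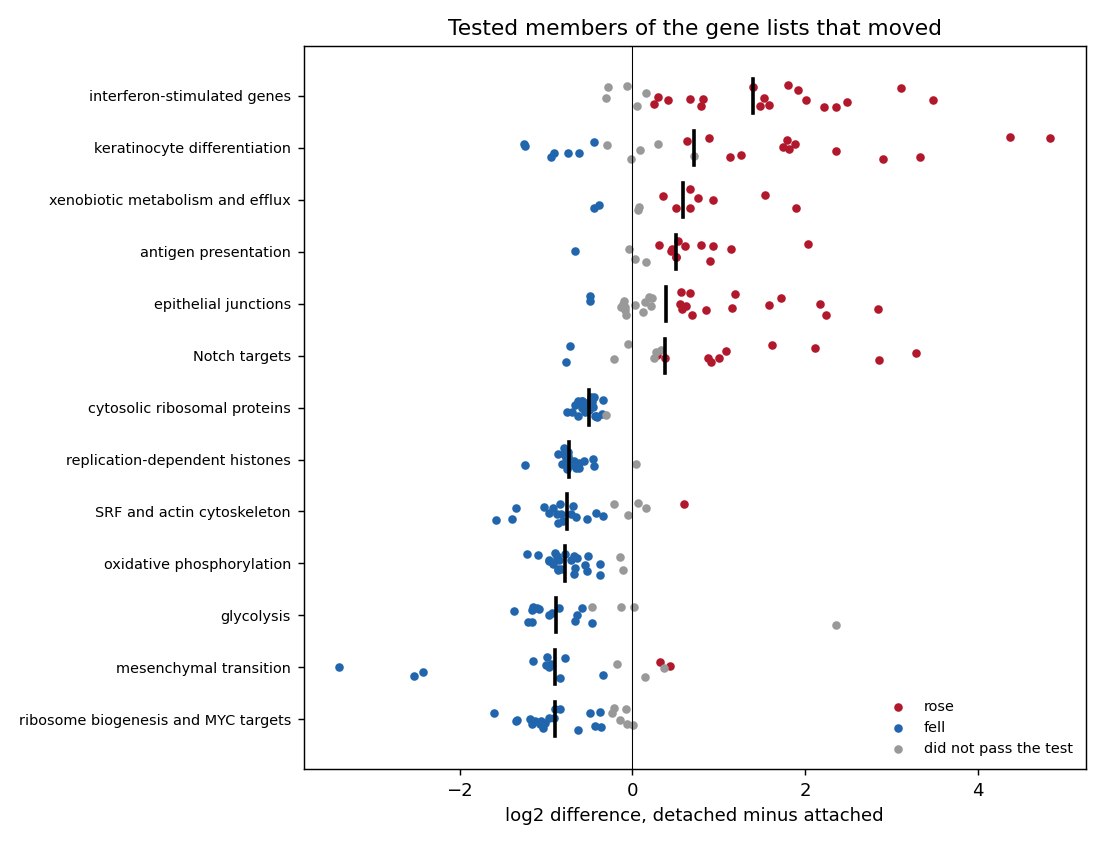
Log2 difference (detached minus attached) of each tested member of the 13 lists that camera called, as points coloured by whether the gene rose, fell or did not pass the test, with the list median as a black line. The interferon list has the highest median (1.40), and the medians of the oxidative phosphorylation, actin and histone lists changed sign on the spike-ins, and that of the ribosomal proteins also with quantile normalization, with cyclic loess and without scaling.

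Interferon-stimulated genes were higher in detached cells. Of 23 tested, 18 rose, 12 of them at least 2-fold, and 0 fell, with a median of 1.40 against -0.12 for random lists of equal brightness (percentile 100, adjusted p = 1.2e-06). The call was lost with adjusted p = 0.262 with an estimated correlation. The median was 0.73 with normexp, 0.73 among probes above background on all arrays and 0.79 with the least changed probe of each gene. RSAD2, an antiviral enzyme, was at least 4.16-fold higher, and the antiviral GTPase MX2 was 8.62-fold higher with detection on 1 of 4 attached arrays. Antigen presentation genes moved with them. Here 12 of 16 rose and only CALR fell, a change that turned under spike-in scaling and cyclic loess (median 0.51, percentile 100, adjusted p = 0.000729, and adjusted p = 0.459 with an estimated correlation). ERAP2 and ERAP1, which trim peptides for class I molecules, rose 4.10-fold and 2.21-fold. The list includes HLA genes, which probes may not separate.

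Among epithelial genes, the lists of junctions and of keratinocyte differentiation were called up, and that of basal squamous genes was called up only with quantile normalization, with cyclic loess and without the filter on dim probes. In the junction list 14 of 28 rose and 2 fell (among them PKP3, which turned without scaling, on the spike-ins, with quantile normalization and with cyclic loess), with a median of 0.39 against -0.34 for random lists (percentile 100, adjusted p = 0.000729, and adjusted p = 0.459 with an estimated correlation). CLDN3, a tight-junction claudin, rose 4.75-fold and TJP3 was at least 2.22-fold higher. The median was 0.22 among probes above background on all arrays. Keratinocyte differentiation genes were mixed. Of 25 tested, 13 rose and 7 fell (median 0.71, or 0.63 with undetected genes at their bound, percentile 99.99, adjusted p = 0.00935, and adjusted p = 0.609 with an estimated correlation). Their median was 0.069 with normexp and 0.19 among probes above background on all arrays. Besides the rises of S100A7 and KRT1, SPRR1B, a precursor of the cornified envelope, fell 2.39-fold, and ECM1 fell 2.38-fold with detection on 2 of 4 detached arrays. Notch pathway genes included 10 that rose and 2 that fell of 17 (median 0.38, percentile 99.03, adjusted p = 0.00177, and adjusted p = 0.459 with an estimated correlation). The receptor NOTCH3 rose 7.24-fold and the target HEYL was at least 3.06-fold higher, while NOTCH4 and NOTCH2 fell, but turned on the spike-ins and did not pass without scaling. Genes of xenobiotic metabolism and efflux included 8 of 12 that rose (median 0.58, percentile 99.64, adjusted p = 0.00954, and adjusted p = 0.399 with an estimated correlation), among them CYP1B1 at 3.72-fold and UGT1A6 at 2.89-fold. With normexp 6 rose and the median was 0.29. GSTP1 and ABCC1 fell, but turned without scaling and on the spike-ins, and GSTP1 also with quantile normalization and cyclic loess.

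The mesenchymal list was lower. Of 16 tested, 11 fell, 5 of them at least 2-fold, and 2 rose (S100A4 and FSTL1), with a median of -0.89 against -0.11 for random lists (percentile 0, adjusted p = 0.0455, and adjusted p = 0.459 with an estimated correlation). VIM was among those that fell. With the replicate number as a block the list was not called (adjusted p = 0.0600), nor was it without attached replicate 4 (adjusted p = 0.0782), with array weights (0.0639), or with the filter on dim probes removed (0.0897) or set to all arrays (0.0548). With camera at the preset correlation its adjusted p ran from 0.000612 to 0.0897. Without scaling and on the spike-ins the median was -0.30 and -0.057, and under each of these 3 members fell and 4 rose. Actin cytoskeleton genes were lower as well except on the spike-ins, with 17 of 22 fallen and CALD1 alone risen (median -0.75, but 0.082 on the spike-ins, percentile 0.51, adjusted p = 0.00191, and adjusted p = 0.459 with an estimated correlation). Without scaling 3 members fell and on the spike-ins 0. Relative to the other genes, camera at the preset correlation still called the actin list down on the spike-ins (adjusted p = 0.00722). A shift of whole arrays hardly changes that comparison, so the call does not test the scaling. PFN1, which binds actin monomers, fell 2.99-fold and ACTN1 2.63-fold.

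Lists of energy metabolism and growth were lower relative to the 75th percentile, and the size and sign of their falls depended on it. On the spike-ins 0 members of the glycolysis, oxidative phosphorylation, ribosome biogenesis and histone lists fell, and the medians were -0.053, 0.049, -0.062 and 0.10. Without scaling 2, 1, 3 and 1 members fell, and the medians were -0.30, -0.19, -0.30 and -0.14. Camera at the preset correlation, which compares a list with the other genes, still called these lists down under both settings. Both settings shift all features of an array by 1 amount, which hardly changes that comparison, so these calls do not test the scaling. On the spike-ins its adjusted p was 0.0135, 0.00102, 0.000685 and 0.00207. In glycolysis 14 of 18 fell and 0 rose (median -0.89, percentile 0.02, adjusted p = 0.00143, and adjusted p = 0.620 with an estimated correlation), with PGAM1 at 2.59-fold and TPI1 at 2.32-fold lower. GPI, which did not pass and was singled out after its values were seen, had a signal of -4.92 on attached array 4 and of 8.32 to 8.41 on the other attached arrays. In oxidative phosphorylation 23 of 25 fell (median -0.79, but 0.049 on the spike-ins, percentile 1.04, adjusted p = 1.8e-05, and adjusted p = 0.523 with an estimated correlation), led by NDUFA9 (2.32-fold) and SDHB (2.14-fold). Ribosome biogenesis and MYC target genes had 19 of 25 fallen, 10 at least 2-fold (median -0.90, percentile 0, adjusted p = 0.000118, and adjusted p = 0.399 with an estimated correlation). Among them ODC1, the first enzyme of polyamine synthesis, fell 3.04-fold and SRM 2.55-fold. Replication-dependent histone genes had 23 of 24 fallen (median -0.74, but 0.10 on the spike-ins, percentile 0.11, adjusted p = 0.00177, and adjusted p = 0.792 with an estimated correlation), although their probes may not separate the near-identical copies. H2AC8 fell 2.36-fold and H2BC15 1.82-fold.

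Cytosolic ribosomal protein genes had 26 of 27 fallen under the main scaling, but their median of -0.50 became 0.021 with quantile normalization, 0.26 with cyclic loess, 0.089 without scaling and 0.33 on the spike-ins. The list was called down (adjusted p = 0.00177, and adjusted p = 0.792 with an estimated correlation), lay at percentile 94.65 of random lists of equal brightness, and was called up with cyclic loess (adjusted p = 0.00208). With camera at the preset correlation its adjusted p ran from 0.000432 to 0.973. The largest fall was that of RPS15 (1.69-fold), which turned on the spike-ins and with cyclic loess.

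**Figure D4:**
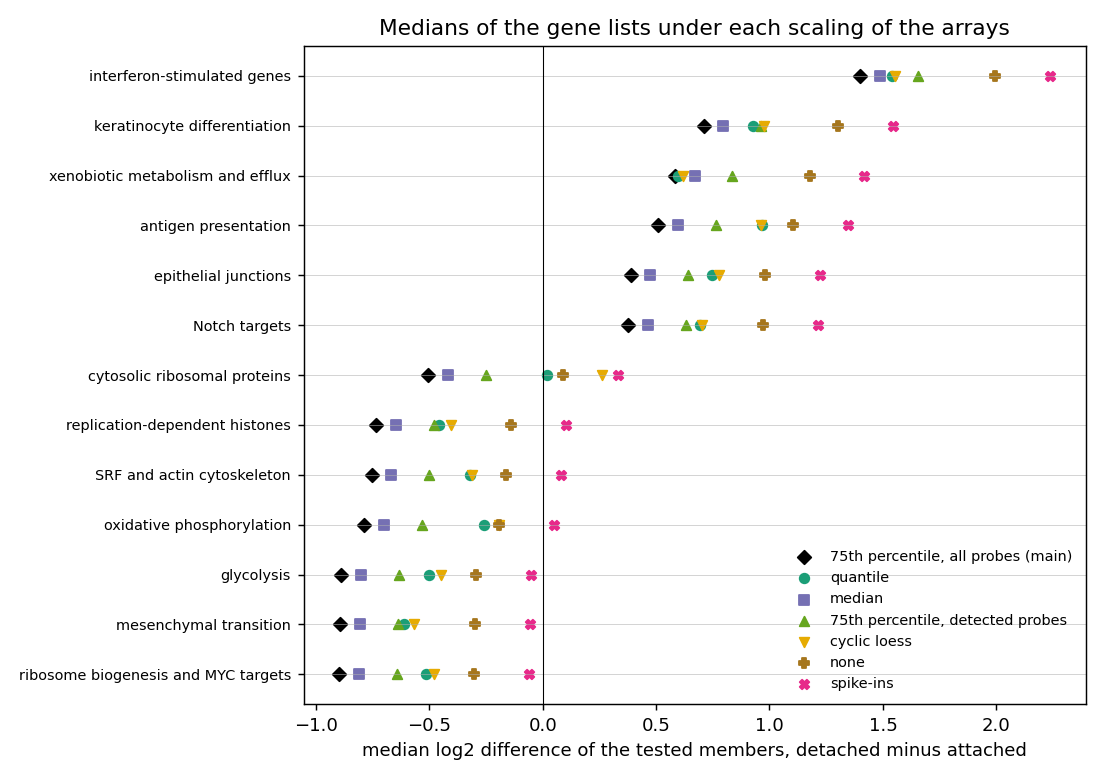
Median log2 difference (detached minus attached) of the tested members of each called list under 7 scalings of the arrays, one symbol per scaling. The interferon median lay between 1.40 and 2.24, while the medians of the oxidative phosphorylation, actin and histone lists turned positive on the spike-ins and that of the ribosomal proteins under 4 scalings.

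The remaining lists were not called. Without the filter on dim probes, camera called 7 of these lists up: integrins (adjusted p = 0.00471), apoptosis (0.00596), basal squamous (0.0181), matrix (0.0236), p53 targets (0.0320), fatty acid synthesis (0.0361) and NF-kB genes (0.0468). For these the adjusted p over settings with the preset correlation reached 0.375, 0.673, 0.737, 0.939, 0.894, 0.744 and 0.964. Without the filter 49536 features were compared, with a median log2 difference of -0.56, against 19886 with -0.18 in the main setting. Camera ranks a list against the other features, so these 7 calls may follow from the added dim probes and not from the lists. Mitotic genes had 4 risen (ASPM, TOP2A, CENPF and KIF11) and 13 fallen of 25, led by CDC20 at 2.34-fold (adjusted p = 0.424), and S-phase genes had POLA1 risen and 16 of 26 fallen, led by UHRF1 at 2.05-fold (adjusted p = 0.101). The medians of both turned under 4 of 7 other scalings and background corrections. Hypoxia genes had 13 of 22 fallen and 2 risen (KDM3A and ZNF395, adjusted p = 0.210), with LOX 6.80-fold and CA9 4.39-fold lower and a median that turned under 2 of 7. The log2 signal of CA9 varied widely among detached arrays (SD 1.21, against 0.11 among attached arrays). The hypoxia list was called down without detached replicate 3 (adjusted p = 0.0233), without scaling (0.00857, median 0.14) and on the spike-ins (0.0119, median 0.38), over a range of 0.00857 to 0.522 with camera at the preset correlation. Targets of p53 had 7 risen and 7 fallen of 19 (adjusted p = 0.728), with TP53INP1 up 3.26-fold, AEN down 2.86-fold and a median that turned under 7 of 7. Immediate early genes had 13 fallen and 3 risen (EGR3, KLF4 and FOSB, the last of which turned under normexp) of 25 (adjusted p = 0.113), with DUSP4 down 5.41-fold and a median that turned under 2 of 7. That list was called down without detached replicate 3 (adjusted p = 0.0464), without scaling (0.0426, median 0.18) and on the spike-ins (0.0432, median 0.43), over a range of 0.0426 to 0.348.

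In lipid metabolism, 13 of 23 cholesterol synthesis genes fell and 3 rose (HMGCS1 and INSIG1 among them, adjusted p = 0.378), and the median turned under 4 of 7 alternatives. Fatty acid synthesis genes had 5 risen (ACSL3, SREBF1, ME1, SCD and LPIN1) and 3 fallen (ELOVL1, ACLY and FADS2, the latter 2 turning on the spike-ins) of 15 (adjusted p = 0.454), and a second SREBF1 probe differed by -0.50. Fatty acid oxidation genes had 4 risen (CPT1A, UCP2 and ACADM among them) and 4 fallen (FABP5, ECI2, HADHA and ECI1) of 12 (adjusted p = 0.804), of which UCP2, detected on 1 of 4 attached arrays, turned under normexp, ECI2 on the spike-ins, HADHA without scaling and on the spike-ins, and ECI1 without scaling, on the spike-ins, with quantile normalization and with cyclic loess. The median of the list turned under 7 of 7.

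Lists of stress responses were not called. ATF4 targets had 16 fallen and 5 risen (NUPR1, SLC7A11, ALDH1L2, CTH and CEBPG) of 24 (adjusted p = 0.247). Genes of the unfolded protein response had 10 fallen and 3 risen (SEL1L, HSP90B1 and EDEM1) of 21 (adjusted p = 0.515), and heat shock genes had 9 fallen of 15 (adjusted p = 0.137), with HSPA8 down 1.95-fold. NRF2 targets had 7 risen and 10 fallen of 23 (adjusted p = 0.708), with AKR1B10 up 5.28-fold and AKR1C1 down 2.43-fold. These medians turned under 2, 5, 4 and 6 of 7 alternatives. Metallothionein and zinc genes had 6 of 9 fallen (adjusted p = 0.210), with MT1E down 2.44-fold and a median that turned under 2 of 7. In the autophagy and lysosome list 15 of 26 fell and 5 rose (GABARAPL1, ULK1, WIPI1, CTSB and UVRAG, adjusted p = 0.428), and the median turned under 3 of 7. Apoptosis genes had 9 risen and 9 fallen of 24 (adjusted p = 0.425), with BIRC3, detected on 2 of 4 attached arrays, up 4.14-fold and BCL2L1, an inhibitor of apoptosis in its long form, down 1.96-fold.

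Among signalling lists, NF-kB cytokines and chemokines had 7 risen and 7 fallen of 20 (adjusted p = 0.636), with CCL5 at least 6.35-fold higher and CSF2 3.59-fold lower. YAP/TAZ targets had 6 risen and 8 fallen of 23 (adjusted p = 0.940), with MYOF up 2.09-fold and AXL down 2.61-fold. TGF-beta targets had 8 fallen and 5 risen (LTBP2, COL1A1, TGFB2, ID3 and ID2) of 19 (adjusted p = 0.804), with PMEPA1 down 4.89-fold. Wnt targets had 7 fallen and 3 risen (AXIN2, FZD7 and TCF7L2) of 12 (adjusted p = 0.636), with AXIN2 at least 1.09-fold higher and BAMBI, detected on 1 of 4 detached arrays, down 3.95-fold. The medians of these 4 lists turned under 5, 5, 3 and 2 of 7 alternatives. Stem cell markers had 5 risen (POU5F1, SALL4, SOX2, KLF4 and ALDH1A3) and 4 fallen (NES, MSI1, CD24 and CD44) of 15 (adjusted p = 0.636), where MSI1 and CD24 turned on the spike-ins and CD44 without scaling, on the spike-ins, with quantile normalization and with cyclic loess, although another CD44 probe differed by -1.91. Their median of 0.068 turned under 1 of 7 alternatives and their mean was -0.0066. Basal squamous genes had 7 risen, led by NGFR at 2.34-fold, and 4 fallen (COL17A1, SFN, CD44 and BNC1) of 18 (adjusted p = 0.454), where SFN and BNC1 turned without scaling and on the spike-ins, and SFN also with cyclic loess. Their median of -0.0093 lay at percentile 99.45 of random lists and turned under 7 of 7 alternatives. The list was called with quantile normalization (median 0.36, adjusted p = 0.0250), with cyclic loess (median 0.42, adjusted p = 0.0142) and without the filter on dim probes (adjusted p = 0.0181), over a range of 0.0142 to 0.737. Median and test differed in sign for the lists of p53 targets, fatty acid oxidation, NRF2 targets, NF-kB genes and basal squamous genes, all 5 of which had medians below 0 and were ranked upward by camera. The means of the NRF2, NF-kB and basal squamous lists lay above 0.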

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

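The tests of the spike-ins, of the filter on dim probes and of leukocyte and fibroblast markers were chosen only after the results they bear on had been seen. The conditions on spread and scaling in the tests of olfactory receptor probes and of cell-type markers were also set after the values were seen.

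In 6 of 138 groups of 4 values 1 array lay far from the other 3, where chance gives about 5%. The 75th percentile of attached 2 was 102 intensity units against 172 to 179 (gap over range 0.907), and the negative-control median of detached 4 was 3.43 against 3.18 to 3.22 (0.858). The mean of the ATF4 list on detached 4 was 3.87 against 3.94 to 3.95 (0.856), that of metallothioneins on detached 4 was 4.71 against 4.96 to 4.98 (0.934), and that of the apoptosis list on attached 2 was 2.46 against 2.51 to 2.52 (0.904). The mean of the glycolysis list on attached 4 was 4.67 against 5.52 to 5.58 (0.941). Without GPI, whose spot on attached 4 read -4.92, that mean was 5.23 on attached 4 and 5.36 to 5.41 on the others. On attached 4 there were 30 probes more than 3 log2 units below every other array although well above background on all of those, and 0 on each of the other 7 arrays.

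The difference between the groups decreased with brightness, with -0.57 from the dimmest to the brightest of 4 bins, although -0.12 with quantile normalization, -0.073 with normexp and 0.40 without a filter on dim probes. Quantile normalization evens out such a trend by design and the normexp offset compresses dim probes, so neither tests it. Response compression on the arrays stays open. The bright spike-ins rose by 0.072 (SE 0.040) relative to the middle ones while genes of the same brightness moved by -0.26. However, spike-ins were lower on detached arrays, by -0.25 to -0.29 for middle and -0.12 to -0.28 for bright ones. Unscaled features were higher there (median 0.42). Compression toward 0 would thus raise bright spike-ins and lower bright genes, so the test cannot argue against it. The weak attached array 2 is argued against by a trend of -0.49 without it. The filter on dim probes may account for part, since the trend was -0.26 among probes above background on all arrays, just under the mark set at 50% of the main value. Genomic DNA stays open, because 0.280% of the olfactory receptor probes dim in attached cells became detected (1 of 357) against 2.71% of other probes, and the exact 95% upper limit of 1.55% lies above 1.35%, the mark set for that test. Detachment itself and the array row, which follows the groups, were not separable by any test.

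Interferon-stimulated and antigen presentation genes were higher in detached cells, although neither list call held with an estimated correlation (adjusted p = 0.262 and 0.459). The brightness trend is argued against by percentiles of 100 for both the interferon and the antigen presentation lists among random lists of equal brightness, and the weak attached array 2 by 16 of the 18 risen interferon genes called without it. The labels name only SAS cells and no source of leukocytes. The marker test alone leaves leukocytes in the samples open, because only 5 of the 14 markers on the array were tested. Their median was -0.65 (SD 0.42), and 0.18 on the spike-ins, where the median of all features was higher (0.66). A baseline such as that of CD4 (5.09 in attached and 4.43 in detached cells) would also hide a small share. Array row and a response to detachment stay open too, as untested.

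As lists, mesenchymal genes were lower and epithelial junction genes higher in detached cells, although neither call held with an estimated correlation (adjusted p = 0.459 for both) and the mesenchymal call was lost with the replicate block (0.0600), with array weights (0.0639) and without attached replicate 4 (0.0782). The brightness trend is argued against by percentiles of 0 and 100 among random lists of equal brightness. Whether a smaller share of fibroblast-like cells could account for it cannot be told apart, because the 7 fibroblast markers went both ways, with a median of 0.064 and an SD of 1.17. The brightest of them, FBLN1, stood at 4.43 in attached and 5.07 in detached cells, and 3 of the 7 are on other lists too. The labels name 1 cell line, and a change within its cells stays open too, as does array row.

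The real split gave 13203 changed features and 3153 changed at least 2-fold. It was the only 1 of the 35 splits with as many of either, and the highest of the others gave 0. Each other split mixed the groups, so the group difference widened the spread within its sides and few calls could pass. Those 0 calls are therefore no measure of chance, and the splits do not exclude it for either count. The 8 splits that part all 4 pairs are too few for a share under 0.05 (smallest 0.125), and the highest of the others among them gave 0 of either. For the 13 lists these splits cannot exclude chance either. As many were given by 7 of the 35 splits, the real one among them, and the highest of the others gave 15. But each of the others with as many kept 3 arrays of 1 group on the same side. Part of the group difference therefore remained in them, and the 15 is no plain chance level. Splits with 2 arrays of each group on either side gave 0 to 4 lists. Among the 8 splits that part all 4 pairs, 3 gave as many lists, the highest of the others again 15. The other 7 of those splits exchange members of some pairs between the groups.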

How the results depend on the processing

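Spike-in scaling, cyclic loess, normexp on the median signal and leaving out the arrays with the lowest and highest 75th percentile together were chosen after seeing the data. The planned normexp on the mean signal and the slide block were not run. Changed features (13203) numbered 8440 without scaling, 7736 on the spike-ins and 27693 without a filter, and 11844 to 14073 with a replicate left out. Higher ones (5119) numbered 7727 without scaling, and 4620 to 5536 with a replicate left out. Lower ones (8084) numbered 5028 with the percentile over detected probes, 713 without scaling, 169 on the spike-ins and 22689 without a filter, and 7224 to 8537 with a replicate left out. At least 2-fold changed (3153) were 5000 without scaling, 6787 on the spike-ins, 4810 without a filter, 2078 with detection on all arrays and 930 with normexp, and 2886 to 3717 with a replicate left out. At least 2-fold higher (1748) were 2781 with the percentile over detected probes, 4788 without scaling, 6644 on the spike-ins, 809 with detection on all arrays and 537 with normexp, and 1666 to 1958 with a replicate left out. At least 2-fold lower (1405) were 912 with quantile normalization, 590 with the percentile over detected probes, 212 without scaling, 143 on the spike-ins, 831 with cyclic loess, 393 with normexp and 2734 without a filter, and 1210 to 1759 with a replicate left out. Lists that moved (13) numbered 0 with an estimated correlation, 33 with fry, and 12 to 15 with a replicate left out. The filter settings change how many features are tested. For the others the cause was not tested.

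With the replicate block 14232 features changed, 3161 at least 2-fold, and 12 lists moved, the mesenchymal list being the 1 call lost. The pairing changed no other list call and no count by over 1.5 times. The ribosomal protein median became 0.021 with quantile normalization and 0.26 with cyclic loess. The p53 (-0.0019) and fatty acid oxidation (-0.0022) lists were called by fry against camera's direction. ECI1 turned to 0.27 with quantile normalization and 0.25 with cyclic loess, SFN to 0.17 and GSTP1 to 0.35 with cyclic loess, and SREBF1 to -0.50 with its least changed probe. Named genes kept call and direction in 4527 comparisons and lost the call in 268, of which 75 were on the spike-ins and 54 without scaling. For lists, called or not, the test kept its side of the threshold in 1011 comparisons, lost a call in 18 and gained one in 33. These counts do not follow the medians, which turned for 23 of the 28 uncalled lists under at least 1 scaling or background correction. Signal over background limits the dim genes, with 37% to 45% of probes detected per array.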

Other observations

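Genes that bind cells to their surroundings changed in opposite directions within 1 family. Of 15 integrins, 7 rose and 4 fell, with ITGB8 up 4.25-fold (log2 difference 2.09, SE 0.11) and ITGA2 at least 1.75-fold higher, and with ITGB5 down 2.94-fold and ITGA5, the fibronectin receptor subunit, down 2.22-fold. The other integrins that fell were ITGA3, which turned on the spike-ins, and ITGA7, which turned without scaling and on the spike-ins. The integrin list was not called (adjusted p = 0.211), except without the filter on dim probes (0.00471, over a range of 0.00471 to 0.375). In that setting the median of all features was lower (-0.56), which by itself ranks a list upward. Matrix and basement membrane genes had 10 risen and 9 fallen of 23 (adjusted p = 0.454, but 0.0236 without the filter on dim probes, over a range of 0.0236 to 0.939). Their median of 0.23 lay at percentile 99.98 of random lists of equal brightness while their mean was -0.048. COL18A1 rose 3.56-fold and LAMA5 1.89-fold, while FN1, fibronectin, fell 3.68-fold and LAMB3, a chain of laminin-332, 2.60-fold. Focal adhesion genes had 13 fallen and 3 risen (TNS3, PDLIM5, another of whose probes differed by -0.19, and FERMT2) of 24 (adjusted p = 0.292, with a median that turned under 3 of 7 alternatives), with TRIP6 down 2.25-fold.

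Matrix proteases were split as well. Of 23 tested, 8 rose and 11 fell (adjusted p = 0.804), with a median that turned under 5 of 7 alternatives. MMP7, matrilysin, rose 8.03-fold and MMP13 was at least 1.26-fold higher, although MMP13 turned under normexp. MMP1, interstitial collagenase, fell 5.12-fold (log2 difference -2.36, SE 0.11).

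Markers of other cell types showed no common rise. Fibroblast markers had 3 risen (DCN, COL1A1 and FBLN1) and 2 fallen (FAP and MMP2, which both turned without scaling and on the spike-ins) of 7 (adjusted p = 0.495). DCN was at least 1.63-fold higher, and COL1A1 was not well above background on any attached array. Leukocyte markers had 0 risen and 3 fallen (CSF1R, CD8A and CD4, the last of which turned on the spike-ins) of 5 (adjusted p = 0.378), with a median that turned under 1 of 7 alternatives. Neural markers had MAP2 risen 5.72-fold, with detection on 3 of 4 attached arrays, and 3 fallen (TUBB3, NEFL and ENO2, the last of which turned on the spike-ins) of 7 (adjusted p = 0.627). Of the endothelial markers 2 could be tested, too few for a list test, and VWF rose 3.04-fold.

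Of the 5904 unnamed probes tested, 1585 were higher and 2244 lower in detached cells, 674 and 444 of them at least 2-fold.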
